A study of Homo sapiens with 9 samples.

How the data were processed

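RNA of the Hodgkin lymphoma cell line L-1236 was measured on human Clariom S arrays, which carry probe sets for transcript clusters of annotated genes. There were 9 arrays in 3 groups of 3. The control group, called v2 after the lentiviral Cas9 vector in its genotype label and wild type in its sample titles, carried no guide against LTA as far as the labels say. Clone g2_1 was made with a guide against the second exon of LTA and clone g3_4 with a guide against the fourth exon. Per the labels' protocols, the knockout clones had been kept in medium conditioned by L-1236 cells, all cells were grown for 72 h in normal medium before RNA was taken, and 250 ng of RNA was labelled. The labels do not say whether the control cells were kept in conditioned medium too or were a single-cell clone, nor whether arrays of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The RNA integrity number was 10 for the array numbered 1 of each group and 9.5 to 9.6 for the others.

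The deposited values are log2 signals after RMA (background correction, quantile normalization and summary of probes), made with Transcriptome Analysis Console 4.0 per the submitters' processing notes. They carry 2 decimals and no detection flags, and no scanner files were used here, so the signal of a probe set cannot be set against its own background. RMA draws all arrays to a similar distribution, which can hide a shift of most genes and which compresses fold changes near the floor of the array. The median of the value table was 6.12 to 6.16 on the knockout arrays and 6.24 to 6.25 on the control arrays, and centring each array on its median raised the median log2 fold change of all transcript clusters from 0.04 to 0.15, a shift of 0.11. Changes are reported on the deposited scale. For arrays, precision is limited by their number.

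The 20893 rows with IDs of transcript clusters were tested, and the 555 rows whose IDs mark them as unmapped were left out, by a rule on IDs written before the data were examined, which took such rows for control probe sets. A gene symbol was found for 17705 tested rows, none had several, and 3188 were unnamed here. All 17705 gene IDs were matched in a RefSeq table of assembly GRCh38.p14, which was used only for names and for which genes neighbour each other, because no build is given in the sources used here. The chromosome in the row ID equalled that of RefSeq for 17695 named rows and differed for 10.

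The values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 coefficient for each group, all 9 arrays, two-sided, no trend, not robust). The comparisons were each clone with control, the mean of both clones with control, and clone with clone. P-values were adjusted by the Benjamini-Hochberg method over all tested transcript clusters, and a transcript cluster was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Means are given with the SD of 3 arrays and fold changes with their moderated standard error (SE). Gene lists, 30 in all with 525 of 599 genes found, were fixed before the data were examined. LTA is in none of them. Each list was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists, beside camera with an estimated correlation and fry. A list member counts as risen or fallen where its adjusted p is under 0.05 in both clones with the same sign. All list counts and directions are of the clones averaged against control unless stated.

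Genes were named by rules written before the data were examined. These take LTA, the 12 largest rises and the 12 largest falls shared by both clones with all knockout arrays on one side of all control arrays, up to 6 genes in each direction that differ between the clones, and up to 2 risen and 2 fallen members of each list, or 4 of each for NF-kB targets, JAK-STAT genes, myeloid genes, neighbours of LTA and ligands of the TNF superfamily. In those 5 lists members that did not pass may be given as values. Genes named outside these rules were chosen after their values were seen, as is said where they appear.

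Arrays with the same number deviated together between the clones (correlation of deviations from the group means 0.435, 0.191 and 0.310 across transcript clusters), so the number pairs the samples of the 2 clones. Against the control the correlations were 0.285, 0.0426 and 0.183 for g2_1 and 0.298, 0.0565 and 0.257 for g3_4. Arrays numbered 1 and 3 thus deviated most like the control array of their number. Arrays numbered 2 deviated more like control array 3 (0.109 for g2_1 and 0.0993 for g3_4). The number therefore pairs the clones with the control only in part, and the main fit used no pairing. Because both comparisons use the same control arrays, unchanged groups were simulated 100 times. The 3 control arrays cannot be split into parts of at least 2 each. On simulated data with 200 changed transcript clusters among 20893, the averaged comparison found 99 of 100 at a log2 size of 1.5 and 100 of 100 at a size of 2, with 0 calls among the unchanged. The simulated noise was independent and alike in all groups, without pairing, an outlying array or a floor. Both sizes lay above the limit on the fold, which also makes false calls rare. The result checks the procedure and does not gauge sensitivity or false calls on the real arrays.

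Alternatives were a replicate block, median centring, another quantile normalization, 2 filters on level, another variance prior, array weights, fits of only the groups compared, RIN as a covariate, a test with unequal variances, other thresholds and leaving out each array. For the clones averaged, the test with unequal variances and the fits of only the groups compared pooled the 6 knockout arrays. A difference between the clones then counts as spread. The test with unequal variances also took each variance from the compared arrays alone, without the variance that limma shares across genes. Chosen after the data were examined were a fit without the arrays numbered 1 and the subtraction of the median fold change of 50 neighbouring expressed genes (mean value over 7). Medians along chromosomes were taken over 50 neighbouring expressed genes, at steps of 10 genes, and compared with 200 shuffles of the genes.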

Results

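The data set compared L-1236, a cell line established from Hodgkin lymphoma, with 2 clones of it in which LTA was targeted with Cas9. LTA encodes lymphotoxin alpha, a secreted cytokine of the TNF superfamily. There were 3 arrays of control cells, 3 of clone g2_1 and 3 of clone g3_4, each with values for the same probe sets. The comparisons address what changes in the transcriptome of the line when LTA is knocked out, with a guide of its own for each clone.

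LTA was examined first, since it checks the labels. Its log2 value was 11.24 ± 0.29 (SD, n = 3) in control cells, 7.54 ± 0.43 in g2_1 and 6.93 ± 0.32 in g3_4. It fell by 3.71 (adjusted p = 1.5e-06) in g2_1 and by 4.31 (adjusted p = 4.2e-07) in g3_4, and all 6 knockout arrays lay below all 3 control arrays. In a test with unequal variances the fall did not pass in g2_1 (adjusted p = 0.0686) and passed in g3_4 (adjusted p = 0.0376). In an exact two-sided permutation test of the 6 knockout against the 3 control arrays, p was 0.0119, the smallest that the 84 splits can give. A transcript with an edited exon need not fall, and which part of LTA the probes cover is not known here. The 50 expressed neighbours of LTA on chromosome 6 had a median change of -0.19 in the clones averaged. Of 13 measured genes beside LTA, 12 did not pass the test and AIF1 fell by 0.86. LTB, which encodes the membrane partner of lymphotoxin alpha, had a log2 fold change of 0.16 (SE 0.10) and did not pass in either clone.

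**Figure D1:**
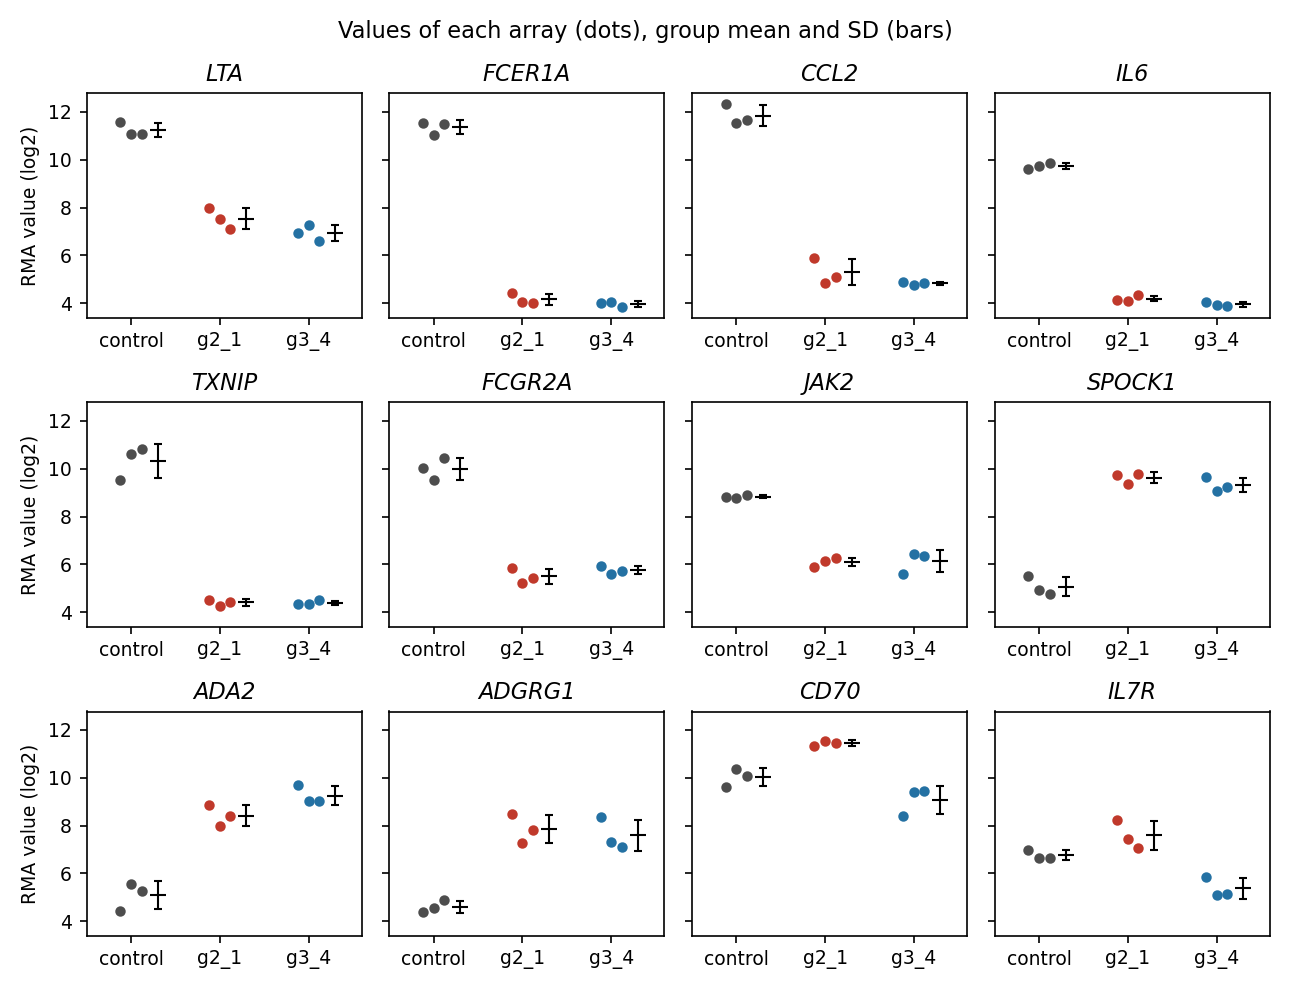
Log2 RMA values of 12 genes on each of the 9 arrays (dots) with the group mean and SD (bars) for control, g2_1 and g3_4, 3 arrays each. LTA lies between 6.61 and 7.97 on the knockout arrays and between 11.07 and 11.58 on the control arrays.

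Against control cells, the largest falls shared by both clones were of genes with high values in the control. FCER1A, the alpha chain of the high-affinity IgE receptor, fell from 11.35 ± 0.29 (SD, n = 3) to 4.18 ± 0.23 in g2_1 and 3.97 ± 0.13 in g3_4, and the monocarboxylate transporter gene SLC16A4 from 11.32 ± 0.24 to 4.34 ± 0.08 and 4.37 ± 0.07. The cytokine gene IL6 fell from 9.73 ± 0.14 to 4.20 ± 0.12 and 3.96 ± 0.09. The clone means of these 3 genes lie under the first quartile of the arrays (4.64), so the size and rank of such falls are bounded by the floor. SULF1, which encodes a heparan sulfate sulfatase, fell by 6.88 (log2, SE 0.18) in the clones averaged from 11.78 ± 0.45, and CCL2, a chemokine that attracts monocytes, from 11.84 ± 0.43 to 5.29 ± 0.55 and 4.84 ± 0.06. The rises were fewer and smaller, led by SPOCK1, which encodes a secreted proteoglycan and was 21.2-fold higher in the clones averaged, and by ADA2, a secreted adenosine deaminase, which was 13.3-fold higher.

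The other large falls of the clones averaged, in log2, were BASP1 at -6.01, RGS2 at -5.96, SORL1 at -5.94, TXNIP at -5.91, CKMT1A at -5.91, APBA1 at -5.84 and CHRNA6 at -5.79. RGS2 encodes a regulator of G protein signalling, SORL1 a sorting receptor, TXNIP a thioredoxin-binding protein and CHRNA6 a subunit of nicotinic acetylcholine receptors. CKMT1A has a near-identical copy in the genome, so its probes may read both. The other large rises were CBR1, a carbonyl reductase, at 3.15, the adhesion receptor gene ADGRG1 at 3.11, MS4A4A at 3.03, RBPMS at 2.82, PIK3CG, which encodes a catalytic subunit of phosphoinositide 3-kinase, at 2.58, the receptor gene CD244 at 2.56, LRRN3 at 2.50, FAM30A at 2.44, ATP8B4 at 2.36 and TLL1 at 2.27. The SE of these averaged changes was at most 0.34, and every adjusted p of these genes in limma was under 0.05 in both clones. In a test with unequal variances that pooled the arrays of both clones, SORL1 (adjusted p = 0.0605), TXNIP (0.0750), MS4A4A (0.134), PIK3CG (0.212), LRRN3 (0.104), ATP8B4 (0.249) and TLL1 (0.0779) did not pass. The pooling counts a difference between the clones, such as that of LRRN3, as spread. These losses need not come from unequal variances alone.

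In g2_1, 873 of 20893 transcript clusters were called in limma, of which 197 were higher and 676 lower than in control cells. In g3_4, 884 were called, 217 higher and 667 lower. The number called the same way in both clones was 752, with 146 higher and 606 lower, and 0 were called in opposite ways. With the clones averaged, 871 were called, 198 higher and 673 lower. The excess of falls depended on the limit on the fold: without it 1294 were higher and 1685 lower in g2_1, 1278 and 1705 in g3_4, and 1698 and 2053 (54.7% lower) with the clones averaged. Falls in both clones of at least 2, 3 and 4 log2 units numbered 262, 143 and 63, against 15, 5 and 1 rises of those sizes. In 29 transcript clusters the control mean was at least 8 and both clone means lay under the first quartile of the arrays (4.64), and in 0 the reverse held, so the size of the deepest falls is bounded by the floor of the array.

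Lists of these lengths drawn independently would share 2.05 higher and 21.6 lower transcript clusters. Groups simulated without any change shared 0.02 on average. Calls are rare there by construction, so that value does not gauge the overlap that shared control arrays give. The log2 fold changes of the clones correlated at r = 0.957 (Spearman's rho 0.822) across transcript clusters, which are not independent replicates, against 0.499 in simulated unchanged groups, and their covariance was 0.285 against 0.0106. The simulated groups were not paired by array number. A drawn regrouping of the real arrays that shared 0 calls had r = 0.909, so a high r alone does not mark shared changes. Part of the excess in overlap may come from the shared controls, which cannot be split here. The lower share of the calls depended on scaling, at 77.3% of calls with the clones averaged on the deposited scale and 66.8% after centring arrays on their median. In a test with unequal variances on the same arrays the counts were far lower, with 30 called in g2_1, 51 in g3_4, 20 the same way in both and 262 with the arrays of both clones pooled. That test also leaves out the variance that limma shares across genes. With few arrays it has few degrees of freedom, so the lower counts do not by themselves show unequal variances.

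**Figure D2:**
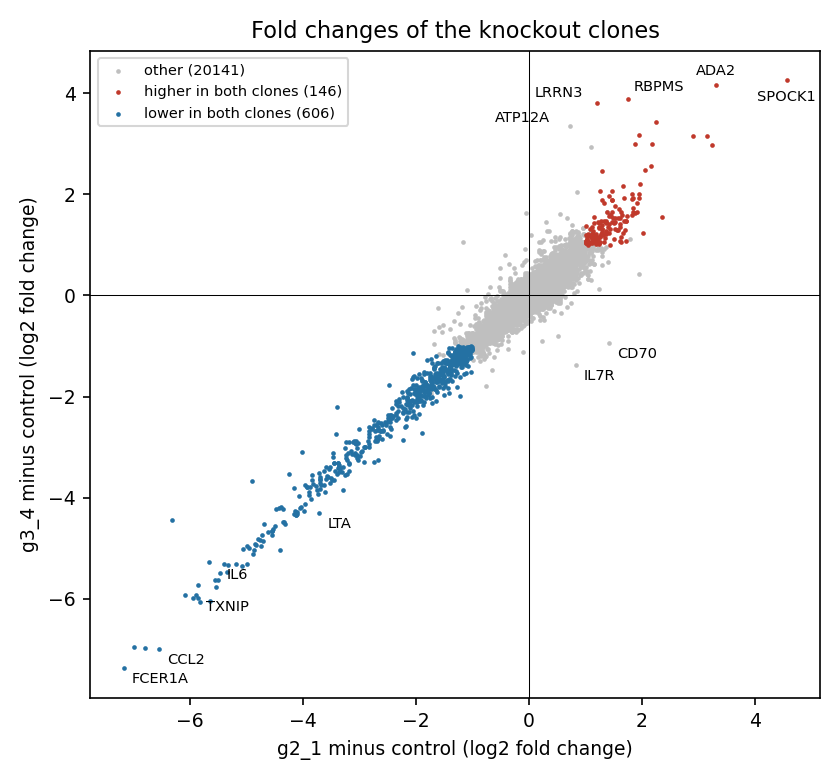
Log2 fold change against control of each of 20893 transcript clusters in clone g2_1 (horizontal) and clone g3_4 (vertical), coloured where called higher (146) or lower (606) in both clones. Most points follow the diagonal, while CD70, IL7R, ATP12A, LRRN3 and RBPMS lie off it.

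Of all 17687 genes with a symbol, 860 (4.86%) rose and 1317 (7.45%) fell by the rule used for list members. List counts near these shares do not set a list apart from other genes. Among targets of NF-kB, the transcription factor family that signals of the TNF superfamily activate, 10 of 33 measured genes fell and 1 rose. IL6 fell by 5.65, CXCL10 fell by 5.36, CD40 fell by 4.78 and CCL3 fell by 3.48 on the log2 scale, and CD83 rose by 0.54. Other members did not pass the test in both clones, among them CCR7 with a log2 fold change of 0.00 (SE 0.08) at a control value of 13.26, TNFAIP3 at 0.33 (SE 0.23), NFKB2 at -0.65 (SE 0.16) and ICAM1 at -0.71 (SE 0.17). Adjusted over the list alone, 14 fell and 3 rose. The list was shifted down in camera (adjusted p = 0.0036), with an adjusted p of 0.608 with an estimated correlation. The call was lost above the median level of all transcript clusters (median -0.13, adjusted p = 0.178), against a median of -0.33 with all of them. That level includes the knockout arrays, so genes can be left out by their own fall. The loss therefore cannot tell whether the shift rests on genes of low level. CXCL10 and CD40 were also higher on control array 1, at 10.92 and 10.53, than on the other control arrays. Of 18 components of the NF-kB pathway, IKBKB, a kinase of the inhibitor of NF-kB, rose by 0.74, while RBCK1 fell by 0.71 and OTULIN fell by 0.50, both of which act on linear ubiquitin chains. Of its members, 2 rose and 3 fell when adjusted over the list alone. That list was not called (adjusted p = 0.634).

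Genes of JAK-STAT signalling moved in both directions, with 5 of 26 risen and 10 fallen. FCER2, the low-affinity IgE receptor CD23, fell by 5.47, PDCD1LG2 fell by 3.33, JAK2 fell by 2.70 and CD274 fell by 2.20 on the log2 scale. PIM1 rose by 1.25, CISH by 0.88 and SOCS3 by 0.79. IL2RA rose from 11.46 in control cells to 12.58 in g2_1 and 12.34 in g3_4. CISH and SOCS3 encode feedback inhibitors of cytokine signalling. JAK2, CD274 and PDCD1LG2, which encode a kinase and both ligands of the receptor PD-1, lie in a part of chromosome 9 whose 50 expressed neighbours had a median of -0.75. Of its members, 8 rose and 11 fell when adjusted over the list alone. The list was not called (adjusted p = 0.294), and its median (0.08) and mean (-0.50) differ in sign, with a downward direction in camera. Among cytokine receptors, 4 of 25 rose and 4 fell: LIFR rose by 1.66 and OSMR by 1.32, while IL13RA1 fell by 5.48 and CSF2RB fell by 1.57. Adjusted over the list alone, 5 rose and 5 fell. That list was not called (adjusted p = 0.975), with a median of 0.07, a mean of -0.14 and an upward direction in camera.

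Chemokines and cytokines fell in 8 of 30 cases, and 1 rose. CCL2 fell by 6.77 and IL6 fell by 5.65, and TGFB1, which encodes a transforming growth factor, rose by 0.54. Of its members, 10 fell and 2 rose when adjusted over the list alone. The list was shifted down in camera (adjusted p = 0.0199), with an adjusted p of 0.328 with an estimated correlation. Of the 28 interferon-stimulated genes, 10 fell and 3 rose. MX1 fell by 3.56 and IFI44L fell by 2.96, and both were higher on control array 1, at 9.54 and 9.08, than on the other control arrays. IFI6 rose by 0.80 and OAS2 by 0.75. Of its members, 11 fell and 5 rose when adjusted over the list alone. The list was not called (adjusted p = 0.430). Ligands of the TNF superfamily other than LTA showed 1 rise among 14, TNFSF10 by 0.79, and 0 falls, while TNFSF9 had a value of -0.57 (SE 0.23) and TNFSF14 of -0.66 (SE 0.23) without passing. Their receptors showed 3 rises and 2 falls among 19. TNFRSF10D rose by 0.90 and TNFRSF8, which encodes CD30, by 0.74, while CD40 fell by 4.78 and CD27 fell by 1.06. Adjusted over the list alone, 2 ligands rose and 0 fell, and 3 receptors rose and 3 fell. Neither list was called (adjusted p = 0.618 and 0.972), and the receptors had a median of 0.04, a mean of -0.22 and a downward direction in camera.

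Genes known from Hodgkin and Reed-Sternberg cells rose in 4 of 26 cases and fell in 8. IRF5 rose by 0.86 and TNFRSF8 by 0.74, and IL13RA1 fell by 5.48 and PDCD1LG2 fell by 3.33. B cell genes rose in 3 of 22 cases and fell in 3: the transcription factor gene EBF1 rose by 1.25 and the kinase gene BLK by 0.89, and POU2AF1 fell by 1.52 and CD37 fell by 0.95. Of their members, 5 rose and 9 fell in the former, and 3 rose and 3 fell in the latter when adjusted over the list alone. Neither list was called (adjusted p = 0.223 and 0.930). The former had a median of 0.02 and a mean of -0.58, with a downward direction in camera, and was called after centring arrays on their median (adjusted p = 0.0475, and adjusted p = 0.336 with an estimated correlation). By clone, camera called the former in g3_4 (adjusted p = 0.0477, and 0.437 with an estimated correlation) and not in g2_1 (0.293). Adhesion molecules rose in 5 of 18 cases and fell in 4. ITGAL, the alpha chain of the integrin LFA-1, rose by 1.66 and CD48 by 1.32, while PECAM1 fell by 5.41 and the hyaluronan receptor gene CD44 fell by 5.15. Of its members, 5 rose and 6 fell when adjusted over the list alone. The list was not called (adjusted p = 0.327).

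Of 13 genes of MHC class I presentation, 4 fell and 0 rose. ERAP2, an aminopeptidase that trims peptides, fell by 3.57 and PSMB9, a subunit of the immunoproteasome, fell by 0.82. The list was not called (adjusted p = 0.294), and the expressed neighbours of PSMB9 on chromosome 6 had a median of -0.34. Of 12 MHC class II genes, HLA-DOA rose by 0.49 and HLA-DOB fell by 0.78. This list was shifted down in camera (adjusted p = 0.0366), with an adjusted p of 0.835 with an estimated correlation, and the call was lost without control array 2 (adjusted p = 0.164), control array 3 (0.130), g2_1 array 1 (0.0693) or g3_4 array 1 (0.086). It was also lost with transcript clusters of the lowest level left out (0.0900), above their median level (0.204) and in fits of only the groups compared (0.187). By clone, camera called the list in g2_1 (median -0.755, adjusted p = 7.1e-04) and not in g3_4 (median -0.0383, adjusted p = 0.848). In g2_1 the adjusted p was 0.627 with an estimated correlation.

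Of 18 genes of the unfolded protein and integrated stress responses, 6 fell and 0 rose. DDIT3 fell by 2.25 and PPP1R15A fell by 1.93. Adjusted over the list alone, 7 fell and 0 rose. The control arrays themselves ranged from 6.82 (array 1) to 9.80 for DDIT3 and from 8.43 (array 1) to 10.37 for PPP1R15A, with the highest value on array 2. Without control array 2 the fall of DDIT3 was 1.65 (adjusted p = 0.051). The list was shifted down in camera (adjusted p = 0.0199), with an adjusted p of 0.831 with an estimated correlation, and the call was lost without control array 2 (adjusted p = 0.148) or control array 3 (0.0929). Without control array 1 the call was kept (adjusted p = 3.0e-06, and 0.525 with an estimated correlation). The same held without the arrays numbered 1 (adjusted p = 1.3e-05, and 0.487 with an estimated correlation). Of 19 genes of cholesterol synthesis, 4 fell and 2 rose. SC5D fell by 3.14 and CYP51A1 fell by 1.52, and DHCR7 rose by 0.60 and PMVK by 0.57. Of its members, 7 fell and 2 rose when adjusted over the list alone. This list was shifted down (adjusted p = 0.0199), with an adjusted p of 0.835 with an estimated correlation, and the call was lost without control array 1 (adjusted p = 0.0744), g2_1 array 1 (0.0683) or g3_4 array 1 (0.0502). It was also lost without the arrays numbered 1 (0.227), with array weights (0.0691), with transcript clusters of the lowest level left out (0.0571) and above their median level (0.178). By clone, camera called the cholesterol list in g3_4 (adjusted p = 0.0146, and 0.836 with an estimated correlation) and not in g2_1 (0.0825).

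Apoptosis regulators fell in 4 of 22 cases and rose in 2. BCL2L11, which encodes the pro-apoptotic protein BIM, fell by 4.11 and BCL2A1, an anti-apoptotic member of the same family, fell by 2.48, while BMF rose by 0.84 and CASP8 by 0.76. With the median of its neighbours subtracted, CASP8 was at 0.39 (adjusted p = 0.0992). Among genes of glycolysis and hypoxia, 5 of 27 fell and 3 rose. ALDOC fell by 2.67 and PFKP fell by 2.05, and NDRG1 rose by 0.62 and PFKL by 0.61. Without control array 3 the rise of PFKL was 0.59 (adjusted p = 0.0504), and without the arrays numbered 1 its value was 0.36 (adjusted p = 0.0849). Of 13 immediate early genes, EGR1 fell by 1.86 and NR4A1 fell by 0.69. Of 19 p53 targets, TRIAP1 rose by 0.56 and TP53I3 by 0.45. The counts were the same for apoptosis and glycolysis, 1 immediate early gene rose and 2 fell, and 3 p53 targets rose when adjusted over the list alone. None of these 4 lists was called (adjusted p = 0.402, 0.975, 0.930 and 0.223) with all arrays, while without control array 3 the p53 targets were called up (adjusted p = 0.0470, and adjusted p = 0.926 with an estimated correlation). Medians and means differed in sign for apoptosis (0.02 and -0.34), glycolysis (0.09 and -0.12) and immediate early genes (0.07 and -0.16), where camera gave down, up and down.

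Of 31 measured genes of proliferation, CDK1 rose by 0.46 and MCM5 by 0.44 and 0 fell, and without control array 2 the rise of CDK1 was 0.36 (adjusted p = 0.0558). With the median of its neighbours subtracted, MCM5 was at 0.19 (adjusted p = 0.229). Adjusted over the list alone, 0 proliferation genes rose or fell. Of 14 genes of ribosome biogenesis UTP20 rose by 0.59, and with its neighbours subtracted it was at 0.34 (adjusted p = 0.0946). Of 16 ribosomal protein genes RPS6, on the same stretch of chromosome 9 as JAK2, fell by 0.53, where its neighbours had a median of -0.77. Of 21 genes of oxidative phosphorylation 0 passed. Of 11 reference genes TFRC rose by 0.86 and GUSB by 0.38. None of these 5 lists was called (adjusted p = 0.402, 0.294, 0.241, 0.402 and 0.223) with all arrays. Without control array 1, which stood apart, proliferation (median 0.21, adjusted p = 0.0158) and reference genes (median 0.13, adjusted p = 0.0407) were called up, with adjusted p of 0.741 and 0.417 with an estimated correlation. They were called up without the arrays numbered 1 too (adjusted p = 0.0415 and 0.0469), with adjusted p of 0.787 and 0.487 with an estimated correlation.

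Markers of other cell types were also examined. Of 31 myeloid genes 4 fell and 0 rose: FCGR2A fell by 4.35, CTSS fell by 2.08, CSF2RB fell by 1.57 and AIF1 fell by 0.86 on the log2 scale. CD14, a marker of monocytes, had a control value of 5.32 and a log2 fold change of -0.03 (SE 0.11). Of 17 markers of T and NK cells, 4 rose and 0 fell. CD2 rose by 1.55 and PRF1, which encodes perforin, by 1.14. The T and NK cell list was shifted up in camera (adjusted p = 0.0199), with an adjusted p of 0.328 with an estimated correlation. Of 12 fibroblast markers ACTA2 rose by 0.95 and FN1 by 0.85, and FAP fell by 1.99. Of 11 plasma cell genes and 7 markers of erythroid cells and platelets 0 passed in both clones. The myeloid, fibroblast, plasma cell and erythroid lists were not called (adjusted p = 0.327, 0.719, 0.975 and 0.686).

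Of the 75 named list members that passed in limma, 24 passed and 51 did not in the test with unequal variances. That test pooled the arrays of both clones, so a difference between the clones counted as spread. It also did without the variance that limma shares across genes. The adjusted p of the 51 was 0.0605 to 0.403. Among the rises these were CD83, IKBKB, PIM1, CISH, SOCS3, OSMR, IFI6, OAS2, IRF5, TNFRSF8, EBF1, BLK, TGFB1, TNFRSF10D, HLA-DOA, CD48, CDK1, UTP20, CASP8, TRIAP1, TP53I3, DHCR7, NDRG1, PFKL, CD2, PRF1, ACTA2 and TFRC. Among the falls they were CXCL10, CD40, CCL3, MX1, IFI44L, CTSS, AIF1, POU2AF1, CD37, CD27, ERAP2, HLA-DOB, PECAM1, BCL2A1, SC5D, CYP51A1, ALDOC, PFKP, DDIT3, PPP1R15A, EGR1, NR4A1 and FAP.

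For the lists given without a count of their own, as many members rose and fell when adjusted over the list alone. Medians and means differed in sign for myeloid genes (0.01 and -0.26, down in camera), B cell genes (0.07 and -0.01, up) and fibroblast markers (0.06 and -0.00333, up). In all, camera called 6 of 30 lists, 5 down and 1 up, and 0 of them held with an estimated correlation. By clone, camera called 5 lists in g2_1 and 6 in g3_4. In fry, which tests whether a list's genes move one way on balance and does not compare a list with other genes, 10 were called with the clones averaged. These held NF-kB targets, chemokines and cytokines, and T and NK cell markers. MHC class II genes (adjusted p = 0.189 in fry), cholesterol synthesis (0.102) and the stress responses (0.102), which camera called, were not among them. The others were JAK-STAT, myeloid, Hodgkin and Reed-Sternberg, MHC class I, adhesion, apoptosis and reference genes, which camera did not call. Among the 84 splits of the 9 arrays into 6 and 3, 18 called at least as many lists as the real one, which called 5 in the same 2-group model, so chance is not excluded for the number of shifted lists.

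**Figure D3:**
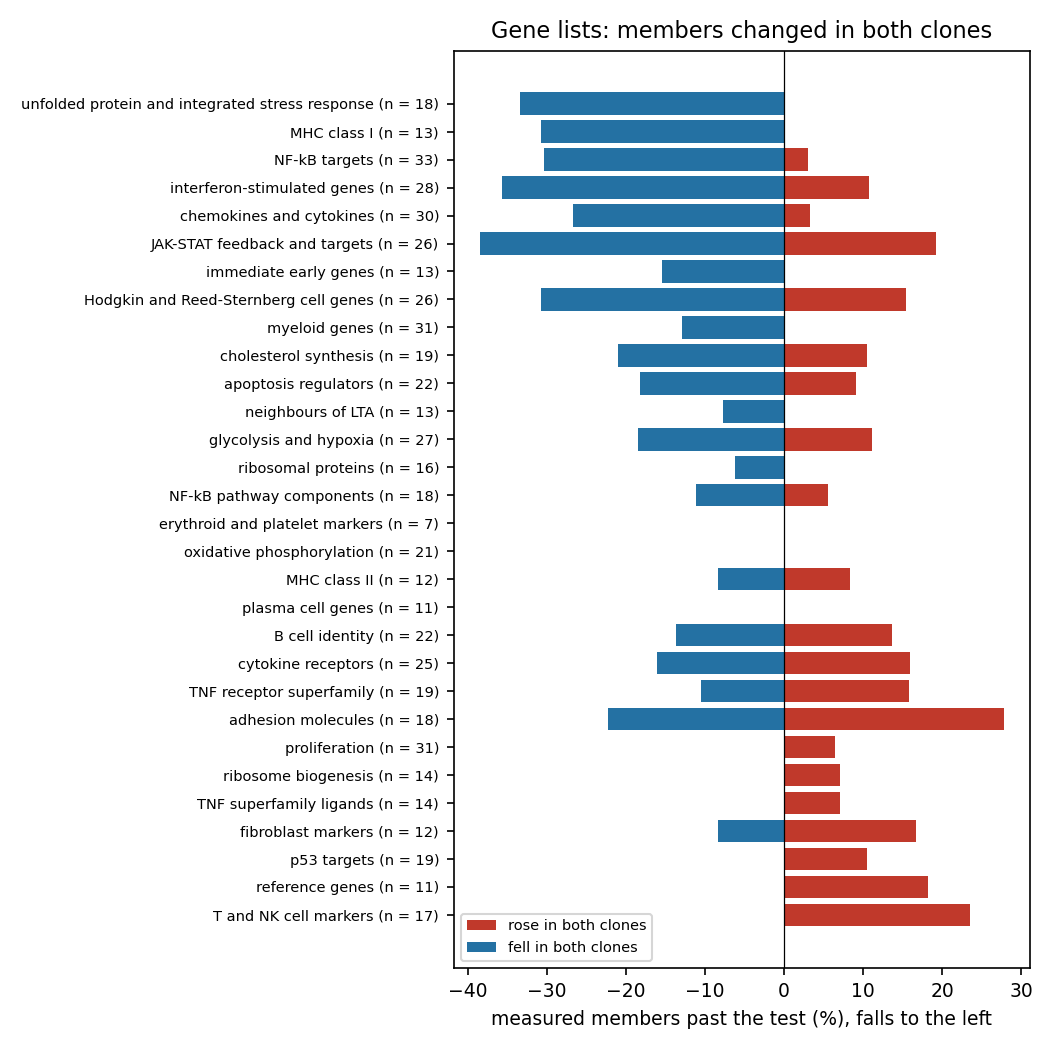
Share of the measured members of each of 30 gene lists that rose (to the right) or fell (to the left) in both clones, in percent of the members measured (n). The falling share is largest for JAK-STAT genes, with 10 of 26, and the rising share for adhesion molecules, with 5 of 18. Of all 17687 genes with a symbol, 4.86% rose and 7.45% fell in both clones.

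The clones were also compared with each other, which separates what belongs to 1 clone from what both share. CD70, a ligand of the TNF superfamily, was higher in g2_1 at 11.43 ± 0.12 (SD, n = 3) than in g3_4 at 9.08 ± 0.58, a difference of 2.35 (SE 0.26, adjusted p = 0.0115), with the control at 10.02 ± 0.38. The interleukin-7 receptor gene IL7R was higher by 2.21 (SE 0.28, adjusted p = 0.0282), the growth factor gene HBEGF by 1.51 (SE 0.20, adjusted p = 0.0303) and GNB4 by 1.11 (SE 0.16, adjusted p = 0.0449). Lower in g2_1 than in g3_4 were ATP12A, a proton pump, by a difference of -2.62, LRRN3 of -2.61, RBPMS of -2.14, MAOA of -1.87, CNTNAP3P2 of -1.36 and NBAS of -0.93. MAOA, a monoamine oxidase, fell in both clones, by 6.31 in g2_1 and by 4.44 in g3_4, and LRRN3 and RBPMS rose in both.

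Of 20893 transcript clusters, 9 were called between the clones in limma, 4 higher and 5 lower in g2_1, and 922 had an unadjusted p under 0.05. With the replicate number as a block, 15 were called, 6 higher and 9 lower, and the 9 were among them. Without control array 1, which enters through the shared estimate of spread, 21 were called, and without g2_1 array 2 or g3_4 array 3, 4 and 5 were. CD70 did not pass without g2_1 array 2 (adjusted p = 0.135) or array 3 (0.0743), and IL7R did not without control array 2 (0.0513), control array 3 (0.0527), g2_1 array 2 (0.166), g3_4 array 2 (0.164) or g3_4 array 3 (0.187). HBEGF and CNTNAP3P2 (0.0527 without control array 3 for each) and NBAS (0.0527) and GNB4 (0.0556), also without control array 3, were lost under further omissions too, up to 0.187 for HBEGF, 0.169 for NBAS and 0.318 for GNB4 without g3_4 array 3 and 0.194 for CNTNAP3P2 without g2_1 array 2. With the median of their neighbours subtracted GNB4 was at 0.73 (0.273) and NBAS at -0.73 (0.118), so that most of each difference remained without passing. ATP12A, LRRN3, RBPMS and MAOA passed under each omission. In the unequal-variance test 0 were called.

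The fold changes were also set out along the chromosomes, a comparison chosen after the values were seen. The expressed genes from HACD4 to FAM201A on chromosome 9 had a median log2 fold change of -0.84 in the clones averaged, with -0.87 in g2_1 and -0.82 in g3_4, and 47 of the 50 genes were lower in g2_1 and 48 in g3_4. Between DNAJC10 and ICA1L on chromosome 2 the median was highest, at 0.41 in the clones averaged, with 44 of the 50 genes higher in g2_1 and 43 in g3_4. On that stretch control array 1 had a median of -0.37 against the other control arrays, with 40 of 50 genes lower, and without it the median of the clones averaged was 0.27, where shuffled windows reached 0.26. On the chromosome 9 stretch the median without it was -0.77. When the genes were shuffled 200 times, window medians lay between -0.21 and 0.32, and 33 of the 708 observed windows lay below and 9 above that range. Neighbouring windows share genes, so these counts are not of separate stretches. Shuffling also breaks any shared regulation of neighbouring genes. The largest difference between the clones was from GMPS to AP2M1 on chromosome 3, at 0.39, where 49 of 50 genes were higher in g2_1.

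**Figure D4:**
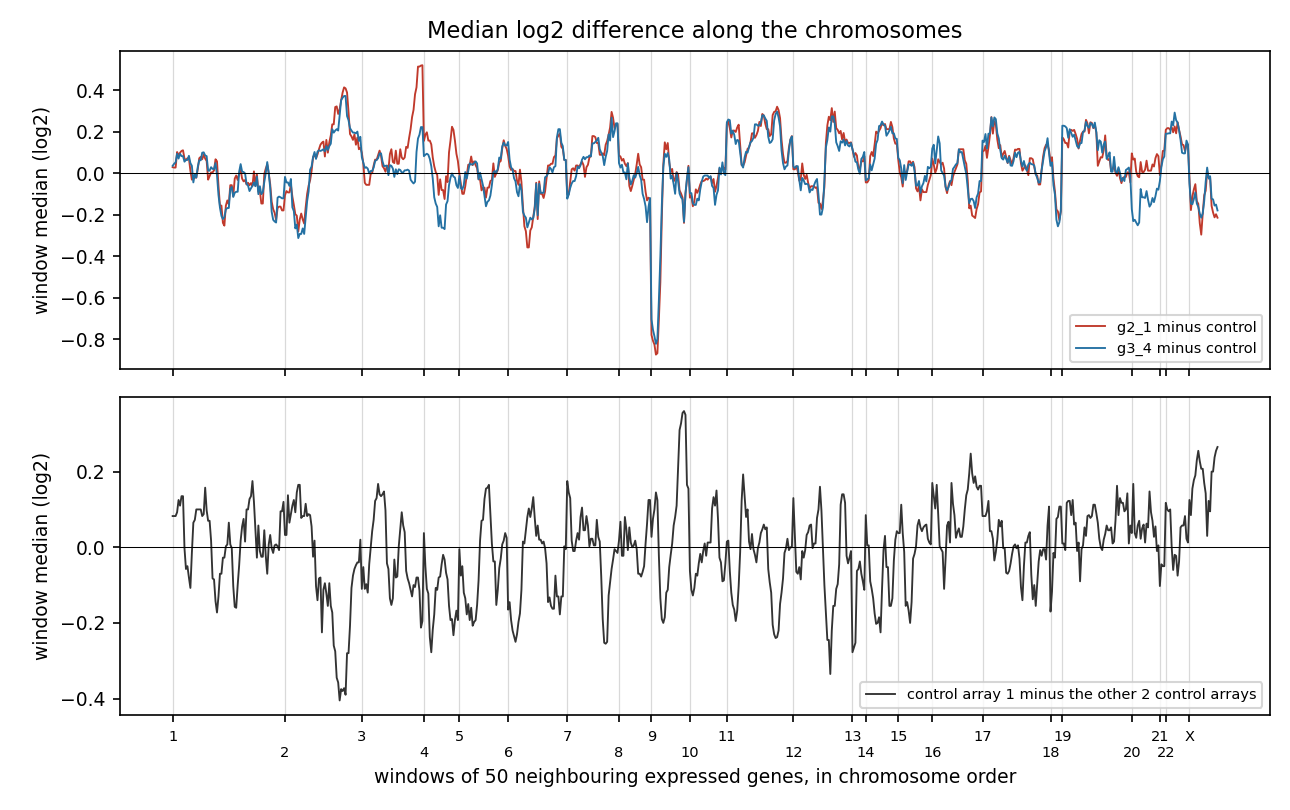
Median log2 fold change of 50 neighbouring expressed genes along the chromosomes, for each clone against control and for control array 1 against the other control arrays. The lowest window of the clones averaged, on chromosome 9, lies at -0.84.

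The arrays of the clones correlated with each other at r = 0.992 to 0.996 across transcript clusters, within and between clones. Control arrays 2 and 3 correlated at 0.995, and control array 1 with them at 0.984 to 0.985. Knockout arrays correlated with control array 1 at 0.953 to 0.957 and with control arrays 2 and 3 at 0.968 to 0.974. On the first principal component, which held 69.9% of the variance, control array 1 lay at 67.0, the other control arrays at 45.7 and 43.2 and the knockout arrays between -27.5 and -24.8. On the second component, which held 11.3%, the arrays numbered 1, those with an RNA integrity number of 10, lay at 28.5 (control), 13.0 (g2_1) and 15.0 (g3_4), and the other 6 arrays lay between -20.5 and -1.86. Without control array 1 the number called with the clones averaged was 752, and without the arrays numbered 1 of all groups it was 733.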

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

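The tests of the deep falls, of the array that stands apart and of a chromosome stretch behind the differences between the clones were chosen after the results were seen.

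The clones differed in 11 named genes by a test of the difference itself (g2_1 minus g3_4, log2). The differences were 2.35 for CD70, 2.21 for IL7R, 1.51 for HBEGF, 1.11 for GNB4, -2.62 for ATP12A, -2.61 for LRRN3, -2.14 for RBPMS, -1.87 for MAOA, -1.36 for CNTNAP3P2, -0.93 for NBAS and -0.82 for EIPR1. Copy number of 1 chromosome stretch as the whole cause was argued against, since 1 of the 11, GNB4, lies in the chromosome 3 stretch that differs most between the clones. With NBAS and EIPR1 on chromosome 2, whose neighbours had a median difference of -0.20, 3 of the 11 lie among neighbours beyond the shuffled range, and with the neighbours' median subtracted GNB4 was at 0.73 (SE 0.16, adjusted p = 0.273), NBAS at -0.73 (adjusted p = 0.118) and EIPR1 at -0.62 (adjusted p = 0.168), so most of each difference remained while the calls, near the threshold before, ended. The call of EIPR1 (adjusted p = 0.0334) was lost without control array 2 (0.0663), control array 3 (0.0618), g2_1 array 2 (0.182) or 3 (0.169), or g3_4 array 1 (0.136), 2 (0.164) or 3 (0.244). Effects of the guide, of the clone and of drift in culture remain open, since each guide is represented by 1 clone. Among the 10 splits of the 6 arrays, the real one called 9 and the highest other 0, and the splits are too few for a share under 0.05. Of the 4 splits that part every pair of arrays with the same number, the real one called 9 and the highest other 0.

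Between the clones 4 gene lists also differed in camera. The median difference was 0.06 for NF-kB targets (adjusted p = 0.0170, and adjusted p = 0.736 with an estimated correlation). It was 0.06 for Hodgkin and Reed-Sternberg cell genes (adjusted p = 0.0338, and adjusted p = 0.510 with an estimated correlation). It was -0.67 for MHC class II genes (adjusted p = 3.03e-16, and adjusted p = 0.478 with an estimated correlation). It was -0.0733 for erythroid and platelet markers (adjusted p = 0.0170, and adjusted p = 0.478 with an estimated correlation).

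The deep falls shared by both clones, 262 of at least 2 log2 units, were weighed against 4 explanations. Copy number of chromosome stretches as the whole cause was argued against, since 23 of the 243 with placed neighbours lie where the neighbours' median is below all shuffled windows (9.47%, against 3.90% of the 17680 transcript clusters placed), which leaves open copy number for part of the falls and loss of single genes or small clusters. Fibroblasts or myeloid cells in the control cultures were argued against, since the 8 abundant transcripts of these cells had a median change of -0.0075, with 0 of 8 fallen. In control cells they ranged from LUM at 4.03, S100A8 at 4.11, LYZ at 4.24, S100A9 at 4.54 and SPARC at 4.77 to COL1A1 at 6.65, TYROBP at 7.48 and COL1A2 at 7.88. These 8 were picked after the results were seen. Of the whole lists, 4 of 31 myeloid genes fell, among them FCGR2A (-4.35) and CTSS (-2.08), and 0 rose. Of 12 fibroblast markers, FAP (-1.99) fell and 2 rose. Descent of both clones from 1 sub-line of the culture may contribute, since both share the chromosome 9 stretch with its median of -0.84, far below the shuffled range. Both clones were compared with the same control arrays, however. A change of the control cells on that stretch would look the same, and these values cannot tell the 2 apart. Loss of LTA itself cannot be told apart from the descent of the clones, whose changes correlated at 0.957, because both come together in each clone, nor from the earlier conditioned medium if the control was not kept in it, which the labels leave unclear.

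Control array 1, which stands apart from the other control arrays, was weighed likewise. It lay farther from the clones than the other control arrays did, as a smaller share of cells like the knockout clones would give, and such a mixture is left open. With the knockout shift taken against control array 2 and that of control array 1 against control array 3, control array 1 moved by 0.202 of minus the knockout shift (95% interval 0.113 to 0.294) at the largest fall and 1.16 (0.646 to 1.99) at the largest rise. A mixture needs equal ratios above 0. With control arrays 2 and 3 exchanged, other stretches were picked. The largest fall then ran from CD274 to ATOSB on chromosome 9, and the largest rise from CDC42EP2 to NDUFV1 on chromosome 11 instead of chromosome 2. The ratios there were 0.0731 (-0.0838 to 0.236) and -0.198 (-0.368 to 0.0507). These intervals overlap, but both include 0, so the overlap does not speak for a mixture and the test cannot decide. RNA quality or handling shared by the arrays numbered 1, as the whole cause, was argued against by a slope of 0.185 of the clones' array 1 shifts on that of the control. Control cultures that differ in chromosome copy number are a candidate explanation, with a lowest window median of -0.41 against a shuffled minimum of -0.27. No biological explanation given by the design was tested, since the array shares its group's labels.

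Other splits of the arrays were counted for the remaining results. The real split called 873 in g2_1 and 884 in g3_4, the highest other of 10 called 0 in each case, and the splits are too few for a share under 0.05. With the clones averaged, 1 of 84 splits, the real one, called as many as 871, and the highest other called 5. That share is the smallest these splits can give. It concerns the labels of the arrays. A chance difference between these cultures is not addressed, since arrays of a group may be technical repeats. For gene lists chance is not excluded: 18 of 84 splits called at least the 5 of the real split, and the highest other, 9, came from 2 splits. In one of these the arrays numbered 1 stood against the rest, and in the other control arrays 2 and 3 with g3_4 array 3 did. With the replicate number as a block in the 3-group model, the clones averaged against control called 6 lists. For the 752 shared by the clones, 1 of 100 drawn partitions, the real one, reached that count, and the highest other reached 733. For the correlation of the clones, 1 of 100 reached 0.957, and the highest other was 0.954. Both of those came from a draw that kept the 3 control arrays together, which points to the control against the clones as the main structure of the arrays.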

How the results depend on the processing

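The fit without the arrays numbered 1 and the subtraction of neighbouring genes were chosen after the data were examined. Named genes kept their side of the threshold, and their direction where they passed in the main fit, in 2276 cases. They were weaker in 134 (74 of them in the unequal-variance test), stronger in 1 and reversed in 1. Lists were kept by the same rule in 547, with 17 weaker and 6 stronger. A change of direction in a gene or list that did not pass in the main fit was not counted. Signal over background limits the values near the floor, for which no detection flags were used. Except where stated, the cause was not tested.

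The number different between the clones (9) was 15 with a replicate block, 21 with array weights, 18 with only the groups compared, 16 with RIN as a covariate, 4 with treat against a fold of 1.5, 4 at an adjusted p under 0.01 and 21 without the arrays numbered 1. The correlation of the clones (0.957) was 0.964 with those of lowest level left out and 0.943 without the arrays numbered 1. A filter at the median level, on means that a deep fall lowers, took averaged falls from 673 to 333 and rises from 198 to 186. Above the median level, where fewer were tested, 525, 535, 431 and 519 were called in g2_1, g3_4, both and averaged, with 3 lists. In the unequal-variance test these were 30, 51, 20 and 262, with 0 between the clones (922 at an unadjusted p under 0.05 in limma), and LTA in g2_1 was -3.71 (adjusted p = 0.0686). With no limit on the fold they were 2979, 2983, 2391 and 3751, and with treat 574, 573 and 491 for the first 3. Camera with an estimated correlation called 0 lists and fry 10. RPS6 reversed to 0.24 when the median of its neighbours was subtracted, by construction.

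Leaving out 1 array at a time gave 782 to 1020 in g2_1, 758 to 1017 in g3_4, 667 to 884 in both, 752 to 1018 averaged, 4 to 21 between the clones, correlations of 0.948 to 0.962, 4 to 7 lists, and LTA at -3.92 to -3.49 in g2_1 and -4.47 to -4.14 in g3_4.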

Other observations

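The genes and comparisons given here were chosen after their values were seen. GSTM1, a glutathione transferase, was at 11.08 in control cells, 6.25 in g2_1 and 6.15 in g3_4, a change of -4.88 with the clones averaged, with GSTM2 at -3.62 and GSTM4 at -2.72. UGT2B17, a glucuronosyltransferase, changed by -4.53 and UGT2B15 by -3.56. Members of each family are similar in sequence, and whether they share probes was not tested. The other members of these families were not counted. The cell cycle inhibitor gene CDKN2A was at 10.47 in control cells and 5.15 in each clone, a change of -5.32 where neighbours on chromosome 9 had a median of -0.79.

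The MHC class II list had a median difference of -0.67 between g2_1 and g3_4, called in camera (adjusted p = 3.03e-16) and not called with an estimated correlation (adjusted p = 0.478). The members given here are 5 of the 12 measured. Against control cells, HLA-DRA was at -0.93 in g2_1 and -0.21 in g3_4, HLA-DRB1 at -1.09 and 0.11, HLA-DQA1 at -1.53 and -0.72, CD74 at -0.84 and -0.14 and their regulator CIITA at -0.73 and 0.02. None of the 12 measured genes differed between the clones at an adjusted p under 0.05 in limma.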
